A study of Escherichia coli str. K-12 substr. MG1655 with 30 samples.

How the data were processed

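RNA was sequenced from 30 cultures of Escherichia coli K-12, in 15 groups of 2 biological duplicates, from MG1655 and from strains lacking atoC, btsR, cusR or rcsB. Per the labels' protocols, cells were taken in mid-exponential growth, rRNA was removed, and stranded libraries were made. Per the submitters' processing notes, Trim Galore, FastQC, Bowtie, featureCounts and MultiQC were used, with versions not given in the sources used here. The genome build and the strand setting of the counting were also not given in the sources used here, so antisense and overlapping genes are uncertain, as are near-identical copies.

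The deposited counts are whole numbers per gene and library, made by the authors without scaling. The deposited log2 TPM values are log2(TPM + 1), in which the TPM of each library sum to 1000000 and 99.2% of the genes were scaled by their length in the reference table to within 1%. Both tables hold 30 columns, all of which were used. A pair of columns, for datoC_M9_acetoacetate_LiCl, carried the same name, with the replicate number 1 in both, and is called replicates a and b here. Of 4355 locus tags, 4351 matched the table of the assembly ASM584v2, from which names and lengths were taken, 4238 of them protein coding and 113 pseudogenes, with no rRNA or tRNA genes among them. Counts at 0 in every library were found for 9 genes.

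Depth ranged from 4689457 to 10721143 counts per library, with a median of 7596403. For counting error only, 3 counts are the upper limit for a gene at 0. The spread between duplicates was wider than counting error, at 1.73 to 48.3 times the variance that counting alone gives. The common biological coefficient of variation was 0.0668.

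Counts were fitted with edgeR 4.0.16 under R 4.3.3 in a single model of 15 group means over all 30 libraries, with TMM factors, the filterByExpr rule (4135 genes tested), 15 residual degrees of freedom and the quasi-likelihood F test. Adjusted p values are Benjamini-Hochberg values of that test within a comparison, with calls at under 0.05. The standard error is the absolute log2 fold change divided by the square root of F. In all, 16 comparisons were made, of which 5 set a deletion strain against wt in the same medium, 2 tested the difference between responses, and the rest followed a supplement or a medium within a strain or compared deletion strains. Gene lists, 51 in number with 875 of 905 members found, were tested where at least 3 members were left, which gave 48 lists. The test was camera (limma 3.58.1) with a preset correlation of 0.01, with Benjamini-Hochberg values over the lists, and again with an estimated correlation. The fry test was also run on each list. Beside the calls over all genes, calls were counted with p values adjusted over the list alone. The design, the lists, the rule for naming genes and the alternatives named below were set before the data were examined.

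Genes were named by a rule. It admits the deleted gene and the members of the lists of the regulator studied. It admits the 8 largest rises and the 8 largest falls among called genes with both libraries on the same side of the other group and a mean of at least 20 CPM in the higher group. For lists with a camera adjusted p under 0.05, or with a large share of members called, it admits up to 4 called members with the largest change and up to 2 that were not called. Genes named fall within this rule, with exceptions chosen after their values were seen. These are flhD, flhC, the levels of cusC and cusA given without a test in M9, and the levels given without a test in the closing part.

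Alternatives were median-of-ratios (RLE) factors, no filter on low counts (4346 genes), a stricter filter with a minimum count of 50 (3680 genes), DESeq2 1.42.0, limma on the deposited log2 TPM, a fit to the libraries of the same medium family only, a term for the replicate number, each reference strain alone for the rcsB comparison, and leaving out each library in turn. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

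The procedure was tested on simulated data with 200 changed genes. edgeR recovered 70.1, 86.2 and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold for the atoC strain against wt with LiCl, and 37.3, 71.6 and 93.9% for the interaction with acetoacetate. It recovered 52.2, 79.1 and 97% for the btsR strain against wt in 0.1x LB, and 47, 74.6 and 95.5% for the interaction with pyruvate. The shares were 62.7, 80.6 and 93.9% for the cusR strain against wt, and 67.2, 86.4 and 93.9% for the rcsB comparison in LB. Between 0.15 and 0.36% of unchanged genes were called. The simulation gave each gene the same spread in every group and drew genes independently of each other. The real duplicates differed in spread between groups, so these shares need not hold for the groups with the widest spread. Nor do the simulated lists stand for lists of genes regulated together. A list of 20 members moved 1.5-fold was called by camera in each of these simulated comparisons, with either correlation, and fry called 5 of 50 unchanged lists for the cusR strain against wt.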

Results

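RNA sequencing measured transcript levels in the Escherichia coli K-12 strain MG1655 (wt) and in 4 strains derived from it, each lacking the gene of a response regulator, the part of a 2-component signalling system that binds DNA. AtoC activates genes for the use of acetoacetate, BtsR responds to pyruvate, CusR to copper, and RcsB to damage of the cell envelope. The 30 libraries form 15 groups of 2 biological duplicates, taken in mid-exponential batch growth per the labels' protocols. Cultures grew in the minimal medium M9, in the rich medium LB, or in LB diluted to 0.1x. Supplements were 10 mM LiCl or acetoacetate with LiCl, 0.5 mM CuSO4, 100 µM pyruvate and 5% ethanol. Groups were named by strain, medium and supplement, so that datoC_M9_LiCl denotes the atoC deletion strain in M9 with LiCl. Of the 15 groups, 5 hold the undeleted strain, and none of these is unsupplemented M9, unsupplemented LB or LB with ethanol.

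Total counts per library ranged from 4689457 to 10721143 over 4355 genes. In the atoC strain they were 9596441 and 9742162 for datoC_M9_acetoacetate_LiCl, 10337070 and 9715307 for datoC_M9_LiCl, 10721143 and 10050752 for datoC_M9. For wt in M9 they were 10369913 and 9699960 for wt_M9_acetoacetate_LiCl, 9567025 and 9247570 for wt_M9_LiCl. In 0.1x LB they were 6005030 and 7002543 for dbtsR_0.1xLB, 7508459 and 8046098 for dbtsR_0.1xLB_pyruvate. For wt there they were 6338396 and 5610581 for wt_0.1xLB, 5860025 and 5355101 for wt_0.1xLB_pyruvate. In LB they were 7684347 and 7014831 for dbtsR_LB, 7258225 and 8655547 for dcusR_LB_CuSO4, 10576254 and 8630514 for dcusR_LB. The rest were 5368966 and 4689457 for drcsB_LB_ethanol, 5153506 and 5418399 for drcsB_LB, 5380889 and 4761240 for wt_LB_CuSO4. Duplicates of a group correlated at a Pearson r of at least 0.9934 over log2 CPM (counts scaled to a library total of 1000000). A gene with 0 counts in a library can lie at up to 3 counts, between 0.255 and 0.847 CPM by library on the scale of the levels, for counting error only. Values in parentheses after a gene are its log2 fold change ± standard error from the edgeR quasi-likelihood test, with 2 libraries per group. Levels are mean CPM ± SD, n = 2, for which library totals were multiplied by their TMM factors of 0.756 to 1.13. Genes are said to rise or fall at an adjusted p under 0.05, and an adjusted p stands beside each named gene that did not pass.

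The deleted genes were read in every library. atoC (b2220) had 0 counts in all 6 libraries of its deletion strain and 13.8 to 314 CPM in the 24 others, at least 43.5-fold lower against a floor of 3 counts per library. cusR (b0571) had 0 counts in all 4 libraries of its strain and 11.9 to 349 CPM in the 26 others, at least 26.6-fold lower. btsR (b2125) had 0 counts in 5 of 6 libraries of its strain and 4 counts in dbtsR_0.1xLB replicate 1, against 12.4 to 85.6 CPM in the 24 others. rcsB (b2217) had 0 counts in 3 of 4 libraries of its strain and 1 count in the remaining library, against 271 to 605 CPM in the 26 others.

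The first question was what AtoC controls where its inducer acetoacetate is present, in M9 with acetoacetate and LiCl. The ato operon, which carries acetoacetate breakdown through acetoacetyl-CoA to acetyl-CoA, was nearly silent without AtoC. atoD (b2221) had 0 counts in both deletion libraries and 61.9 ± 4.69 CPM in wt, at least 195-fold lower. atoE (b2223, -6.17 ± 0.29), the acetoacetate importer gene, and atoB (b2224, -4.74 ± 0.18), for acetyl-CoA acetyltransferase, fell, with atoE at 0.733 ± 0.0116 against 54 ± 1.81 CPM. atoS (b2219, -0.51 ± 0.12), for the partner sensor kinase, fell slightly. All 4 ato operon genes fell (4 lower when adjusted over the list alone, camera adjusted p = 1.4e-08).

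A larger group than the operon was motility. All 54 flagellar and chemotaxis genes tested fell (54 lower when adjusted over the list alone, camera adjusted p = 2.8e-92), among them the aspartate receptor gene tar (-7.54 ± 0.22), the flagellar sigma factor gene fliA (-7.21 ± 0.19) and the flagellin gene fliC (-6.89 ± 0.10). fliC stood at 47.9 ± 0.461 CPM in the deletion strain and 5691 ± 717 in wt. The rod and basal body genes flgB (-6.99 ± 0.23) and fliF (-6.67 ± 0.18) fell as well. Of 39 genes of anaerobic respiration and fermentation, 27 rose (30 higher when adjusted over the list alone, camera adjusted p = 5.04e-16), led by the nitrate reductase genes narI (2.38 ± 0.13), narJ (2.28 ± 0.12) and narH (1.35 ± 0.10). The formate-dependent nitrite reductase gene nrfB (1.26 ± 0.11) and the periplasmic nitrate reductase gene napB (1.47 ± 0.14) were also higher. All 8 histidine biosynthesis genes rose (8 higher when adjusted over the list alone, camera adjusted p = 6.99e-13), such as hisI (1.73 ± 0.10), hisF (1.68 ± 0.09) and hisA (1.34 ± 0.07).

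Among 29 genes of the RpoS general stress response, 24 fell (1 higher and 27 lower when adjusted over the list alone, camera adjusted p = 6.99e-13), including msyB (-1.07 ± 0.10), glaH (-0.82 ± 0.18) and talA (-0.72 ± 0.08). Iron uptake genes under Fur went down in 21 of 38 cases and up in 5 (6 higher and 22 lower when adjusted over the list alone, camera adjusted p = 0.0016), with fes (-1.14 ± 0.10), efeB (-1.11 ± 0.14) and fiu (-1.10 ± 0.10) lowest. In the TCA cycle 11 of 16 genes fell (12 lower when adjusted over the list alone, camera adjusted p = 6.2e-07, and adjusted p = 0.26 with an estimated correlation), for example sdhB (-0.77 ± 0.07) and acnA (-0.63 ± 0.07). Type 1 fimbriae rose in 6 of 9 genes (7 higher when adjusted over the list alone, camera adjusted p = 0.00022), with fimC (0.93 ± 0.11) and fimD (0.83 ± 0.08). Sugar uptake genes under CRP rose in 19 of 39 (20 higher when adjusted over the list alone, camera adjusted p = 2.5e-06), with gatD (0.99 ± 0.10) and gatC (0.85 ± 0.07). The copper efflux gene cusA (1.44 ± 0.08) was higher too. cusC of the same operon stood at 2649 and 2599 CPM in the deletion strain against 2309 and 2562 in wt, levels given without a test. The edgeR test found 530 genes higher and 515 lower in the deletion strain, 36 and 100 of them at least 2-fold. These numbers were 296 higher and 359 lower with only the libraries of the same medium family in the fit. The numbers were 299 higher and 567 lower with limma on the deposited log2 TPM. Leaving out 1 library gave a total (with rises and falls of at least 2-fold) of 1204 (69 and 113) without wt_M9_acetoacetate_LiCl replicate 2.

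**Figure D1:**
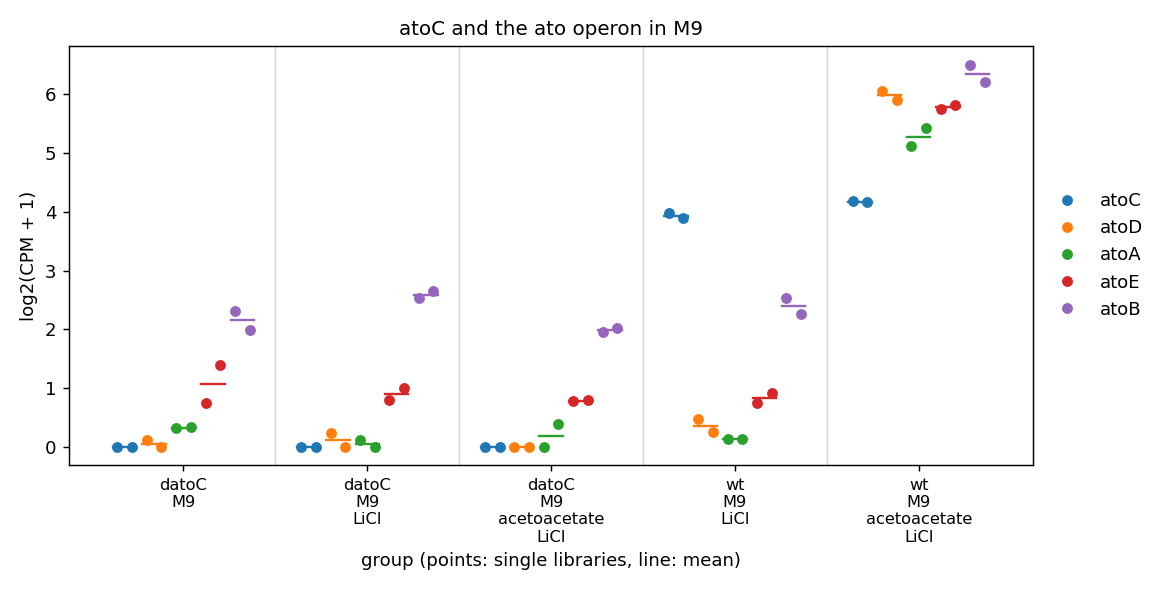
Levels of atoC and the 4 ato operon genes as log2(CPM + 1) on a linear axis in each library of the 5 M9 groups, with points for single libraries and a line at the mean of 2. The operon genes stand highest in wt_M9_acetoacetate_LiCl, with atoE at 54 CPM there and 0.733 CPM in datoC_M9_acetoacetate_LiCl.

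In M9 with LiCl alone, the control for the supplement, deletion of atoC left atoB (0.22 ± 0.23, adjusted p = 0.53) of the ato operon without a detected change. It stood at 5.03 ± 0.336 CPM in the deletion strain and 4.29 ± 0.698 in wt, and atoE, nearer the floor, at 0.874 ± 0.195 and 0.791 ± 0.153 CPM. Motility genes were again low, and all 54 fell (54 lower when adjusted over the list alone, camera adjusted p = 3.9e-99). Examples were tar (-8.06 ± 0.21), fliC (-7.27 ± 0.11), the motor gene motA (-7.18 ± 0.16) and the dipeptide receptor gene tap (-6.75 ± 0.17). fliC stood at 55.3 ± 1.29 CPM against 8542 ± 108. Nitrate reductase genes were higher, as narJ (2.76 ± 0.13), narH (2.38 ± 0.10), narI (2.29 ± 0.14), napB (2.26 ± 0.15) and napH (1.84 ± 0.11) show, within 28 of 39 anaerobic genes that rose (30 higher and 1 lower when adjusted over the list alone, camera adjusted p = 2.7e-16). All 8 histidine genes rose (8 higher when adjusted over the list alone, camera adjusted p = 9.1e-10), with hisF (1.58 ± 0.09) and hisA (1.34 ± 0.08) leading.

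Genes under CpxR, which responds to envelope stress, fell in 9 of 15 cases (9 lower when adjusted over the list alone, camera adjusted p = 0.00014), with cpxP (-1.53 ± 0.11), yqjA (-0.97 ± 0.16) and the protease gene htpX (-0.86 ± 0.06). Sulfate assimilation fell in 11 of 24 genes (2 higher and 14 lower when adjusted over the list alone, camera adjusted p = 0.00016, and adjusted p = 0.087 with an estimated correlation), including the transport genes cysU (-1.59 ± 0.11), cysW (-1.44 ± 0.11) and cysP (-1.26 ± 0.11). Acid resistance genes of the Gad system rose in 12 of 17 cases (12 higher when adjusted over the list alone, camera adjusted p = 0.00018, and adjusted p = 0.087 with an estimated correlation), with their activator gene gadE (1.37 ± 0.26) and the efflux genes mdtF (0.80 ± 0.08) and mdtE (0.72 ± 0.13). Fimbrial genes rose in 6 of 9 cases (6 higher when adjusted over the list alone, camera adjusted p = 0.00085), such as fimI (1.00 ± 0.11), fimC (0.90 ± 0.10) and fimD (0.88 ± 0.08). The siderophore genes fiu (-1.19 ± 0.10), fes (-1.10 ± 0.10) and fepD (-1.06 ± 0.16) fell, within 18 lower and 3 higher of 38 iron uptake genes (4 higher and 19 lower when adjusted over the list alone, camera adjusted p = 0.0045, and adjusted p = 0.087 with an estimated correlation). The sodium and proton antiporter gene chaA (-0.85 ± 0.11) was lower, and the aspartate transcarbamoylase genes pyrB (1.18 ± 0.10) and pyrI (1.07 ± 0.08) were higher. In total 549 genes rose and 484 fell, 41 and 104 at least 2-fold. The counts became 256 higher and 327 lower with only the libraries of the same medium family in the fit. The total became 552 without datoC_M9_LiCl replicate 2, 679 without wt_M9_LiCl replicate 1 and 647 without wt_M9_LiCl replicate 2.

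Adding acetoacetate to the LiCl medium of wt addresses what the strain with AtoC does when the inducer arrives. The largest responses were in the ato operon. All 4 of its genes rose (4 higher when adjusted over the list alone, camera adjusted p = 8.3e-16), with atoE (b2223, 6.07 ± 0.28) and atoB (b2224, 4.22 ± 0.17), the latter from 4.29 ± 0.698 to 80.4 ± 11.7 CPM. The regulator genes atoC (0.25 ± 0.12, adjusted p = 0.21) and atoS (0.12 ± 0.12, adjusted p = 0.597) did not pass. The pyruvate transporter gene btsT (2.78 ± 0.28) rose from 12.2 ± 0.148 to 83.7 ± 5.42 CPM. Histidine genes rose in 7 of 8 cases (8 higher when adjusted over the list alone, camera adjusted p = 2.7e-10), such as hisH (0.75 ± 0.09) and hisA (0.71 ± 0.08). Arginine genes rose in 6 of 13 (9 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00011, and adjusted p = 0.086 with an estimated correlation), such as argC (0.65 ± 0.09) and carA (0.58 ± 0.09). Purine genes purK (0.64 ± 0.10) and purM (0.61 ± 0.10) and the isomeroreductase gene of branched-chain amino acid synthesis, ilvC (0.75 ± 0.08), were higher.

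Of 54 flagellar genes 27 fell (34 lower when adjusted over the list alone, camera adjusted p = 2.9e-10), with motA (-0.86 ± 0.09) and the hook-associated gene flgK (-0.76 ± 0.08). The alanine exporter gene alaE (-1.29 ± 0.19), the tryptophan transporter gene mtr (-1.07 ± 0.12), ilvG (-0.91 ± 0.08) of the branched-chain amino acid list and the gluconate transporter gene gntT (-0.88 ± 0.10) went down. Iron uptake genes rose in 10 of 38 cases (15 higher when adjusted over the list alone, camera adjusted p = 0.00011). The maltose transport genes malK (0.68 ± 0.09) and malF (0.52 ± 0.09) and the nitrate reductase gene narH (0.73 ± 0.10) also rose. The test gave 202 genes higher and 146 lower, 8 and 4 by at least 2-fold. The split was 51 higher and 44 lower with only the libraries of the same medium family in the fit. The numbers were 84 higher and 93 lower with limma on the deposited log2 TPM. With 1 library left out, the total (with rises and falls of at least 2-fold) was 147 without wt_M9_LiCl replicate 1, 160 without wt_M9_LiCl replicate 2, 228 (11 and 1) without wt_M9_acetoacetate_LiCl replicate 1 and 985 (12 and 39) without wt_M9_acetoacetate_LiCl replicate 2.

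The same addition to the atoC strain asks which changes need no AtoC. Here atoE stayed near the floor, at 0.874 ± 0.195 and 0.733 ± 0.0116 CPM, and atoB (-0.75 ± 0.25) fell, from 5.03 ± 0.336 to 2.98 ± 0.121 CPM. That fall was lost without datoC_M9_LiCl replicate 1 or replicate 2 (adjusted p = 0.088 and 0.21) and without datoC_M9_acetoacetate_LiCl replicate a or replicate b (0.17 and 0.11), and its adjusted p ranged from 0.032 to 0.21 over all alternatives. The rise of btsT (2.78 ± 0.28) was there too, from 12 ± 0.697 to 82.8 ± 8.41 CPM. All 8 histidine genes rose (8 higher when adjusted over the list alone, camera adjusted p = 5.5e-14), with hisB (1.05 ± 0.09) and hisC (1.00 ± 0.08). Arginine genes rose in 9 of 13 cases (10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 7.9e-08), with argC (0.84 ± 0.09), carA (0.82 ± 0.09) and argD (0.76 ± 0.08). The lysine gene lysA (1.20 ± 0.12), the asparagine synthetase gene asnA (1.05 ± 0.07) and ilvC (1.02 ± 0.08) were higher. Of 17 purine genes 9 rose (12 higher when adjusted over the list alone, camera adjusted p = 1.6e-07, and adjusted p = 0.087 with an estimated correlation), for example purK (0.92 ± 0.10) and purL (0.65 ± 0.07). Genes under CpxR rose in 7 of 15 cases (8 higher when adjusted over the list alone, camera adjusted p = 7.96e-06), with cpxP (1.21 ± 0.11) and htpX (0.51 ± 0.06).

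The acid resistance regulator genes gadE (-1.73 ± 0.26), gadW (-0.87 ± 0.13) and gadX (-0.86 ± 0.14) fell, as did the regulator gene appY (-1.39 ± 0.17) and the nucleoid protein gene stpA (-0.81 ± 0.11). General stress genes fell in 18 of 29 cases (19 lower when adjusted over the list alone, camera adjusted p = 1.7e-10, and adjusted p = 0.086 with an estimated correlation), such as yeaG (-0.52 ± 0.08), osmY (-0.51 ± 0.09) and wrbA (-0.50 ± 0.09). The phosphate uptake gene pstS (-0.58 ± 0.11) and the aldehyde reductase gene yqhD (-0.71 ± 0.12) were lower. Altogether 314 genes were higher and 262 lower, 13 and 19 at least 2-fold. Other settings gave 113 higher and 96 lower (8 and 9 at least 2-fold) with only the libraries of the same medium family in the fit. They were 109 higher and 460 lower (4 and 13 at least 2-fold) with limma on the deposited log2 TPM. DESeq2 gave 8 and 9 at least 2-fold. Single libraries moved the total (with rises and falls of at least 2-fold) to 423 (23 and 15) without datoC_M9_LiCl replicate 1, 262 without datoC_M9_LiCl replicate 2, 422 (13 and 33) without datoC_M9_acetoacetate_LiCl replicate a and 435 (20 and 13) without datoC_M9_acetoacetate_LiCl replicate b.

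A test of the difference between these responses, over 8 libraries, asks which of them depended on AtoC. The response of atoE (b2223, -6.31 ± 0.76) and atoB (b2224, -4.97 ± 0.30) was lower in the deletion strain. The acid resistance activator gene gadE (-2.18 ± 0.37), the regulator gene appY (-1.50 ± 0.24), stpA (-1.04 ± 0.15) and the nitrate reductase gene narH (-1.02 ± 0.14) also responded less, or in the other direction, without AtoC. The difference was positive for the stress-related gene ychH (1.49 ± 0.25), which fell in wt from 85.7 ± 0.0569 to 50 ± 7.31 CPM and rose in the deletion strain from 50.9 ± 11.2 to 84 ± 19.5. It was positive also for htpX (0.67 ± 0.08) and hisC (0.78 ± 0.12), which rose in the deletion strain and did not pass in wt (adjusted p = 0.079 and 0.105). The difference was also positive in 5 of 15 genes under CpxR (8 higher when adjusted over the list alone, camera adjusted p = 1.99e-05). DESeq2 gave no adjusted p for atoE and atoB here. atoC itself, at 0 counts in the deletion strain, was not tested for a response. In all, the difference was positive for 109 genes and negative for 102, 13 and 18 at least 2-fold. These numbers were 10 higher and 7 lower (2 and 6 at least 2-fold) with only the libraries of the same medium family in the fit. The numbers were 29 higher and 102 lower (5 and 10 at least 2-fold) with limma on the deposited log2 TPM. DESeq2 gave 9 and 11 at least 2-fold. Leaving out 1 library gave a total (with rises and falls of at least 2-fold) of 256 (30 and 15) without datoC_M9_LiCl replicate 1, 69 (4 and 10) without datoC_M9_LiCl replicate 2, 114 without datoC_M9_acetoacetate_LiCl replicate a, 270 (34 and 17) without datoC_M9_acetoacetate_LiCl replicate b, 91 (8 and 13) without wt_M9_LiCl replicate 1, 113 without wt_M9_LiCl replicate 2, 146 (6 and 22) without wt_M9_acetoacetate_LiCl replicate 1 and 784 (73 and 26) without wt_M9_acetoacetate_LiCl replicate 2.

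LiCl against no supplement in M9 was compared in the atoC strain, so it gave the lithium salt response without AtoC only. The periplasmic chaperone gene cpxP (2.50 ± 0.12) rose most, from 71.8 ± 18.6 to 408 ± 6.01 CPM. Of 15 genes under CpxR 11 rose (11 higher and 1 lower when adjusted over the list alone, camera adjusted p = 4.1e-13), including yebE (1.25 ± 0.10), the diguanylate cyclase gene dgcZ (1.04 ± 0.12) and ldtC (1.04 ± 0.09). Of 38 iron uptake genes 25 rose (28 higher when adjusted over the list alone, camera adjusted p = 2.2e-15), such as entC (1.47 ± 0.15), fes (1.33 ± 0.12), fhuF (1.27 ± 0.09) and fepD (1.22 ± 0.20). Sulfate assimilation rose in 13 of 24 genes (14 higher when adjusted over the list alone, camera adjusted p = 3.1e-13), with cysJ (1.44 ± 0.10), cysP (1.37 ± 0.12) and cysD (1.31 ± 0.12). Arginine genes rose in 12 of 13 cases (12 higher when adjusted over the list alone, camera adjusted p = 4.1e-11), with carB (1.07 ± 0.08) and carA (0.92 ± 0.09). Pyrimidine genes rose in 10 of 17 (10 higher when adjusted over the list alone, camera adjusted p = 3.7e-06), with codA (0.48 ± 0.07).

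Some copper genes were higher as well, namely cusC (1.26 ± 0.09), cusR (1.08 ± 0.08), cueO (0.57 ± 0.11), hprR (0.64 ± 0.11) and hprS (0.63 ± 0.13). The pump operon did not rise as a whole: cusA stood at 1018 and 1006 CPM with LiCl against 1188 and 1255 without, levels given without a test. In the list of CueR and copper homeostasis genes 5 of 11 rose (7 higher when adjusted over the list alone, camera adjusted p = 0.0023). Nitrogen limitation genes rose in 6 of 22 cases (7 higher when adjusted over the list alone, camera adjusted p = 2.8e-05), with hisJ (0.56 ± 0.08), glnL (0.53 ± 0.08) and glnG (0.51 ± 0.07). TCA cycle genes rose in 13 of 16 cases (16 higher when adjusted over the list alone, camera adjusted p = 9.6e-12, and adjusted p = 0.078 with an estimated correlation), with sdhC (0.65 ± 0.13) and sdhA (0.54 ± 0.07). The nitrate genes narG (0.79 ± 0.11) and narK (0.76 ± 0.09) rose, and the ribose gene rbsD (-1.12 ± 0.19) fell. atoB (0.52 ± 0.23, adjusted p = 0.14) did not pass. The edgeR count was 333 higher and 226 lower, 33 and 23 at least 2-fold. The counts became 134 higher and 43 lower (28 and 6 at least 2-fold) with only the libraries of the same medium family in the fit. They were 217 higher and 144 lower (24 and 10 at least 2-fold) with limma on the deposited log2 TPM. DESeq2 gave 29 and 8 at least 2-fold. The total (with rises and falls of at least 2-fold) became 255 (32 and 7) without datoC_M9 replicate 1, 297 without datoC_M9 replicate 2, 525 (34 and 45) without datoC_M9_LiCl replicate 1 and 177 (28 and 1) without datoC_M9_LiCl replicate 2.

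BtsR activates the pyruvate transporter gene btsT in rich medium, and its deletion was compared with wt in 0.1x LB. btsT (b4354, 1.19 ± 0.36) stood at 25.7 ± 23.3 CPM in the deletion strain and 11 ± 0.972 in wt. Its duplicates in the deletion strain were far apart, at 42.2 and 9.20 CPM, and without dbtsR_0.1xLB replicate 1 its value was -0.27, the other direction. It did not pass without wt_0.1xLB replicate 1 (adjusted p = 0.15) or without wt_0.1xLB replicate 2 (adjusted p = 0.17), and its adjusted p ranged from 1.2e-10 to 0.55. The sensor kinase gene btsS (-0.29 ± 0.12, adjusted p = 0.16) did not pass, nor did yhjX (0.17 ± 0.18, adjusted p = 0.63), the target of the related pyruvate sensing system. Flagellar genes fell in 30 of 54 cases (33 lower when adjusted over the list alone, camera adjusted p = 4.5e-34), with tar (-4.28 ± 0.21), tap (-3.70 ± 0.20), cheA (-3.02 ± 0.16), motA (-2.96 ± 0.18) and fliA (-2.67 ± 0.20) among them. tar was at -5.31 without dbtsR_0.1xLB replicate 1 and -3.63 without replicate 2. fliC (-2.52 ± 0.09) was at 137 ± 8.35 CPM against 784 ± 26.4. Type 1 fimbriae rose in 5 of 9 genes (6 higher when adjusted over the list alone, camera adjusted p = 2.9e-07), with fimA (1.56 ± 0.07), fimC (1.49 ± 0.15) and fimI (1.37 ± 0.13).

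Phosphate limitation genes rose in 8 of 16 cases (8 higher when adjusted over the list alone, camera adjusted p = 7.5e-05), such as pstC (0.82 ± 0.10), pstS (0.78 ± 0.08) and phoU (0.68 ± 0.08). Acid resistance genes rose in 12 of 17 (14 higher when adjusted over the list alone, camera adjusted p = 5.5e-05, and adjusted p = 0.0598 with an estimated correlation), with yhiM (0.71 ± 0.09) and gadC (0.62 ± 0.10). Methionine genes fell in 6 of 15 (1 higher and 7 lower when adjusted over the list alone, camera adjusted p = 7.2e-05), with metN (-1.07 ± 0.10), metI (-0.76 ± 0.13) and metB (-0.51 ± 0.10). The sulfate gene cysP (-0.84 ± 0.16), the tryptophan gene trpE (-0.97 ± 0.18) and the acetolactate synthase genes ilvN (-0.97 ± 0.11) and ilvB (-0.69 ± 0.07) were lower. The outer membrane protein gene yiaD (1.31 ± 0.15), the purine transporter gene punC (1.25 ± 0.09) and the uracil salvage gene upp (0.68 ± 0.11) rose. Ribosomal protein genes rose in 13 of 54 cases (19 higher when adjusted over the list alone, camera adjusted p = 1.1e-07, and adjusted p = 0.26 with an estimated correlation), for example rpsJ (0.40 ± 0.07). The test gave 323 higher and 176 lower genes, 30 and 33 at least 2-fold, or 14 and 37 with a share of the dcusR_LB_CuSO4 profile subtracted from dbtsR_0.1xLB replicate 1, chosen after seeing the data. The split was 560 higher and 365 lower with only the libraries of the same medium family in the fit. The numbers were 178 higher and 205 lower with limma on the deposited log2 TPM. With 1 library left out, the total (with rises and falls of at least 2-fold) was 286 (14 and 36) without dbtsR_0.1xLB replicate 1, 262 without dbtsR_0.1xLB replicate 2, 193 (15 and 30) without wt_0.1xLB replicate 1 and 288 (18 and 26) without wt_0.1xLB replicate 2.

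With pyruvate, the signal of the system of BtsS and BtsR, in 0.1x LB, btsT (b4354, -0.85 ± 0.41, adjusted p = 0.14) was at 8.18 ± 0.0841 CPM in the deletion strain against 14.7 ± 0.299, which did not pass. btsS (b2126, -0.55 ± 0.13) was lower, with an adjusted p = 0.078 without wt_0.1xLB_pyruvate replicate 2, over a range of 0.00053 to 0.078 for all alternatives, and yhjX (0.08 ± 0.18, adjusted p = 0.799) did not pass. Ribosomal protein genes rose in 43 of 54 cases (45 higher when adjusted over the list alone, camera adjusted p = 9.2e-21), such as rplW (0.90 ± 0.11), rpsJ (0.77 ± 0.07) and rplC (0.75 ± 0.10). Flagellar genes fell in 30 of 54 (31 lower when adjusted over the list alone, camera adjusted p = 8.1e-18), with tar (-4.34 ± 0.22), tap (-3.52 ± 0.20), motA (-3.16 ± 0.19), fliA (-2.98 ± 0.22) and fliC (-2.22 ± 0.09), where tar was at -4.93 without dbtsR_0.1xLB_pyruvate replicate 2. Fimbrial genes rose in 6 of 9 (6 higher when adjusted over the list alone, camera adjusted p = 1.1e-07), with fimC (1.68 ± 0.15) and fimA (1.63 ± 0.07). Genes for the breakdown of fatty acids fell in 8 of 10 cases (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 2.8e-05), with fadB (-0.77 ± 0.09) and fadL (-0.76 ± 0.06). The hexose phosphate transporter gene uhpT (-1.97 ± 0.13), the acetyl-CoA synthetase gene acs (-0.96 ± 0.10) and the peptide and pyruvate transporter gene cstA (-0.85 ± 0.06) fell.

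Nitrogen limitation genes fell in 15 of 22 cases (15 lower when adjusted over the list alone, camera adjusted p = 5.1e-05), such as ddpX (-1.06 ± 0.14), argT (-0.85 ± 0.07) and astC (-0.84 ± 0.09). Tryptophan genes fell in 7 of 11 (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 3.1e-05), such as trpD (-1.40 ± 0.13), trpE (-1.35 ± 0.15) and mtr (-1.01 ± 0.12). Phosphate limitation genes rose in 9 of 16 and fell in 1 (10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 5.3e-05), with pstS (1.25 ± 0.08) and pstC (1.07 ± 0.10) higher. Sugar uptake genes under CRP fell in 17 of 39 (19 lower when adjusted over the list alone, camera adjusted p = 4.3e-06), such as mglC (-1.18 ± 0.12) and lsrA (-1.11 ± 0.07). The cold shock genes cspG (2.18 ± 0.47) and cspB (1.67 ± 0.41), the regulator gene rcsA (1.42 ± 0.28) and pyrD (1.18 ± 0.10) of pyrimidine synthesis were higher. In this comparison 532 genes rose and 464 fell, 54 and 55 at least 2-fold.

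**Figure D2:**
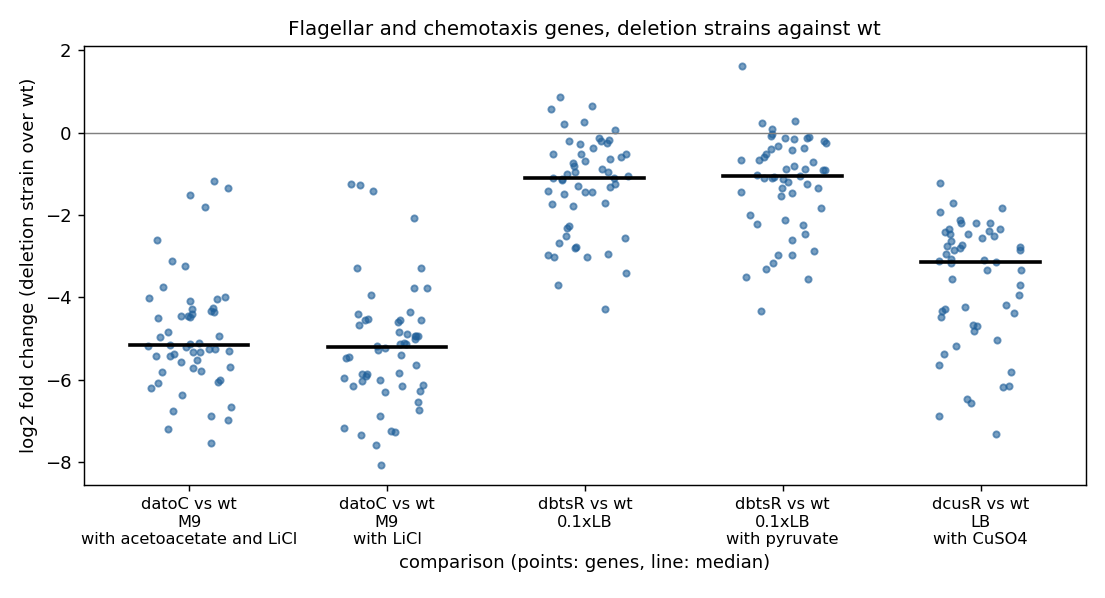
Log2 fold changes (deletion strain over wt) of the 54 flagellar and chemotaxis genes in the 5 comparisons with wt, 1 point per gene from 2 libraries per group and a line at the median. All 54 lie below 0 in both atoC comparisons and with copper, with medians of -5.17, -5.20 and -3.14.

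Pyruvate against no supplement was compared within each strain in 0.1x LB. In wt, btsT (b4354, 0.42 ± 0.40, adjusted p = 0.67) went from 11 ± 0.972 to 14.7 ± 0.299 CPM, and neither it nor yhjX (-0.10 ± 0.19, adjusted p = 0.86) passed. Nitrogen limitation genes rose in 11 of 22 cases (15 higher when adjusted over the list alone, camera adjusted p = 2.5e-08), with the glutamine synthetase gene glnA (0.89 ± 0.08) and the regulator gene glnG (0.55 ± 0.09). Tryptophan genes rose in 7 of 11 and fell in 1 (7 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0013), with mtr (0.93 ± 0.12), trpD (0.85 ± 0.13) and trpB (0.64 ± 0.09) higher. Genes of fatty acid breakdown rose in 7 of 10 (8 higher when adjusted over the list alone, camera adjusted p = 0.00011), with fadL (0.41 ± 0.06) and fadD (0.40 ± 0.07), and acs (0.58 ± 0.10) rose with them. The nickel and cobalt response gene rcnR (1.40 ± 0.17) and the arabinose regulator gene araC (0.74 ± 0.10) were higher. Heat shock genes fell in 8 of 21 cases (10 lower when adjusted over the list alone, camera adjusted p = 6.99e-07, and adjusted p = 0.12 with an estimated correlation), with the disaggregase gene clpB (-0.51 ± 0.08). The galactitol genes gatD (-0.61 ± 0.10) and gatR (-0.53 ± 0.08) and the glycolate gene glcD (-0.64 ± 0.10) fell. The test gave 151 higher and 65 lower genes, 5 and 3 at least 2-fold. Other settings gave 292 higher and 277 lower with only the libraries of the same medium family in the fit. They were 50 higher and 88 lower with limma on the deposited log2 TPM. Single libraries moved the total (with rises and falls of at least 2-fold) to 83 (2 and 2) without wt_0.1xLB replicate 1, 60 (4 and 1) without wt_0.1xLB replicate 2, 64 (3 and 1) without wt_0.1xLB_pyruvate replicate 1 and 61 (3 and 0) without wt_0.1xLB_pyruvate replicate 2.

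The same was asked of the strain without BtsR. There, pyruvate was followed by lower sugar uptake genes, 19 of 39 under CRP (28 lower when adjusted over the list alone, camera adjusted p = 3.6e-22), with gatD (-0.73 ± 0.10) among them. Replicate 1 of dbtsR_0.1xLB, on the side without pyruvate, held an excess of transcripts abundant in dcusR_LB_CuSO4, described in a later part. The list was not tested again with that excess subtracted, which left 66 genes lower over all genes. The tryptophanase operon genes tnaA (-1.58 ± 0.24) and tnaB (-1.17 ± 0.14) and the glycolate oxidase gene glcE (-0.83 ± 0.11) fell, and the peptidoglycan gene ldtE (0.44 ± 0.06) rose slightly. tnaA stood at 340.2 and 120.4 CPM in the duplicates without pyruvate, and its value was -0.65 without dbtsR_0.1xLB replicate 1. The edgeR count was 20 higher and 87 lower, 1 and 17 at least 2-fold, or 2 and 1 at least 2-fold with a fixed share of the dcusR_LB_CuSO4 profile subtracted from dbtsR_0.1xLB replicate 1, an alternative chosen after seeing the data, under which tnaA was at -0.76. These numbers were 222 higher and 267 lower with only the libraries of the same medium family in the fit. The numbers were 6 higher and 39 lower with limma on the deposited log2 TPM. Leaving out 1 library gave a total (with rises and falls of at least 2-fold) of 26 (0 and 2) without dbtsR_0.1xLB replicate 1, 83 (3 and 29) without dbtsR_0.1xLB replicate 2, 24 (0 and 3) without dbtsR_0.1xLB_pyruvate replicate 1 and 21 (0 and 3) without dbtsR_0.1xLB_pyruvate replicate 2.

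The test of the difference between both pyruvate responses, over 8 libraries, found lower responses without BtsR in several groups. Nitrogen limitation genes, which rose in wt, had a negative difference in 11 of 22 cases (15 lower when adjusted over the list alone, camera adjusted p = 3.01e-08), with glnA (-0.79 ± 0.11) and argT (-0.69 ± 0.09). So did the lists for fatty acid breakdown, 4 of 10 (7 lower when adjusted over the list alone, camera adjusted p = 2.8e-05), and tryptophan, 4 of 11 (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 7.2e-05), which also rose in wt. CRP-dependent sugar genes, which fell without BtsR, had a negative difference in 14 of 39 (19 lower when adjusted over the list alone, camera adjusted p = 4.4e-12), with malE (-0.90 ± 0.16). That of the transporter gene cstA (-0.66 ± 0.08) was negative too, and yhjX (-0.09 ± 0.26, adjusted p = 0.93) did not pass. None of these lists was tested again with the excess in dbtsR_0.1xLB replicate 1 subtracted. The difference was positive for 12 genes and negative for 79, 3 of the latter at least 2-fold. The counts became 19 higher and 122 lower with DESeq2. They were 220 higher and 226 lower with only the libraries of the same medium family in the fit. The numbers were 19 higher and 20 lower with limma on the deposited log2 TPM. The total (with rises and falls of at least 2-fold) became 34 (0 and 1) without dbtsR_0.1xLB replicate 1, 93 (2 and 29) without dbtsR_0.1xLB replicate 2, 30 (0 and 1) without dbtsR_0.1xLB_pyruvate replicate 1, 30 without dbtsR_0.1xLB_pyruvate replicate 2, 38 (1 and 1) without wt_0.1xLB replicate 1, 25 without wt_0.1xLB replicate 2, 32 without wt_0.1xLB_pyruvate replicate 1 and 24 without wt_0.1xLB_pyruvate replicate 2.

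Diluting LB to 0.1x was followed in the btsR strain, the only one grown in both. The pyruvate-induced transporter gene yhjX (b3547, -8.22 ± 0.14) fell most among the genes tied to pyruvate sensing, from 4749.8 ± 345 to 16 ± 1.00 CPM, and btsS (b2126, -2.57 ± 0.11) fell. Genes that ran high in dilute medium were those of propionate use, prpD (11.90 ± 0.23) and prpC (11.66 ± 0.26), with prpD at 3219 ± 112 against 0.826 ± 0.0248 CPM. ymgC, a small gene under RcsB, had 0 counts in both LB libraries and 136 ± 2.31 CPM in 0.1x LB, at least 335-fold higher. All 29 RpoS-dependent genes rose (29 higher when adjusted over the list alone, camera adjusted p = 1.9e-14), including glaH (10.19 ± 0.16), lhgD (8.94 ± 0.14) and gabT (8.49 ± 0.12). So did all 17 acid resistance genes (17 higher when adjusted over the list alone, camera adjusted p = 2.5e-08), with the antiporter gene gadC (9.73 ± 0.16). All 16 phosphate limitation genes rose (16 higher when adjusted over the list alone, camera adjusted p = 3.8e-06), with phoH (7.45 ± 0.13) and ugpB (6.14 ± 0.12).

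Iron uptake genes rose in 31 of 38 and fell in 1 (31 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.1e-07), with bfd (7.77 ± 0.20) and fhuF (7.57 ± 0.13). Nitrogen limitation genes rose in 18 of 22 and fell in 3 (18 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0011), led by the arginine breakdown genes astC (9.88 ± 0.18) and astA (9.38 ± 0.14). Fatty acid breakdown rose in 9 of 10 genes and fell in 1 (9 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0011), with fadE (5.34 ± 0.10) and fadB (5.17 ± 0.14). Anaerobic genes fell in 37 of 39 and rose in 1 (1 higher and 37 lower when adjusted over the list alone, camera adjusted p = 5.4e-12), such as narG (-8.32 ± 0.17), narH (-8.22 ± 0.14) and nrfA (-8.18 ± 0.15). The hybrid cluster protein gene hcp (-10.36 ± 0.14), its reductase gene hcr (-8.74 ± 0.19) and the threonine breakdown gene tdcA (-8.59 ± 0.24) were also far lower. All 9 glycerol genes fell (9 lower when adjusted over the list alone, camera adjusted p = 0.00012, and adjusted p = 0.18 with an estimated correlation), with glpT (-8.14 ± 0.20). Without dbtsR_0.1xLB replicate 1, tdcA was at -9.20 and glpT at -8.74, and without dbtsR_LB replicate 1 astA was at 10.05. All 9 ATP synthase genes were lower (9 lower when adjusted over the list alone, camera adjusted p = 0.00033, and adjusted p = 0.072 with an estimated correlation), with atpE (-2.25 ± 0.08). In total 1678 genes rose and 1712 fell, 1139 and 1076 at least 2-fold. The split was 1247 higher and 2112 lower with limma on the deposited log2 TPM.

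CusR activates a copper and silver efflux pump, and its deletion was compared with wt in LB with CuSO4. The pump operon was the most changed. cusC (b0572, -12.09 ± 0.17), for the outer membrane channel, was at 0.869 ± 0.0402 CPM against 3848 ± 30.9 in wt. cusB (b0574, -10.49 ± 0.23) and cusA (b0575, -8.36 ± 0.12) fell with it. cusF (b0573) was at 0.868 ± 0.888 CPM against 2879 ± 77, and the sensor kinase gene cusS (b0570) at 0.705 ± 0.362 against 167 ± 9.88, near the floor in the deletion strain. All 6 CusR target genes, cusR included, were lower (6 lower when adjusted over the list alone, camera adjusted p = 5.9e-09). The copper exporter gene copA (b0484, 1.29 ± 0.19) of the CueR system was higher, at 19465 ± 631 against 7968 ± 263 CPM, as was the copper oxidase gene cueO (b0123, 0.80 ± 0.11). hprR (-2.37 ± 0.13), hprS (-2.40 ± 0.16) and hiuH (-3.57 ± 0.16), which a paralogous peroxide sensing system controls, were lower. The zinc and envelope stress chaperone gene zraP (5.91 ± 0.24) and the threonine and lysine breakdown genes tdcG (5.22 ± 0.29) and cadA (4.35 ± 0.32) were among the highest.

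Motility was low, with all 54 genes down (54 lower when adjusted over the list alone, camera adjusted p = 1.4e-27), such as fliC (-7.32 ± 0.11), tar (-6.88 ± 0.21) and motA (-6.56 ± 0.19). Of 54 ribosomal protein genes 53 fell (53 lower when adjusted over the list alone, camera adjusted p = 2.5e-19), for example rpsQ (-1.82 ± 0.09) and rplP (-1.55 ± 0.09). All 16 TCA cycle genes fell (16 lower when adjusted over the list alone, camera adjusted p = 8.3e-15), with sdhB (-3.95 ± 0.07) and sdhA (-3.83 ± 0.08). The cytochrome oxidase genes cyoC (-5.13 ± 0.08) and cyoD (-5.01 ± 0.09) fell within 15 lower and 3 higher of 19 aerobic respiration genes (3 higher and 15 lower when adjusted over the list alone, camera adjusted p = 3.6e-07). Anaerobic genes rose in 31 of 39 and fell in 1 (32 higher and 1 lower when adjusted over the list alone, camera adjusted p = 6.9e-13), with dmsB (4.01 ± 0.12) and dmsA (2.94 ± 0.13). Genes under CpxR rose in 14 of 15 (14 higher when adjusted over the list alone, camera adjusted p = 7.4e-10), with yebE (3.45 ± 0.11) and spy (2.34 ± 0.14). Iron uptake genes fell in 27 of 38 and rose in 1 (1 higher and 27 lower when adjusted over the list alone, camera adjusted p = 2.7e-07), with fiu (-4.83 ± 0.10) and efeO (-4.83 ± 0.16). Iron-sulfur assembly genes fell in 14 of 16 (14 lower when adjusted over the list alone, camera adjusted p = 3.3e-08), with iscR (-3.36 ± 0.09). Sulfate genes rose in 14 of 24 and fell in 2 (15 higher and 2 lower when adjusted over the list alone, camera adjusted p = 5.8e-06), with cysI (3.82 ± 0.15). In this pair 1029 genes rose and 1005 fell, 265 and 440 at least 2-fold. Other settings gave 1457 higher and 839 lower with limma on the deposited log2 TPM.

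**Figure D3:**
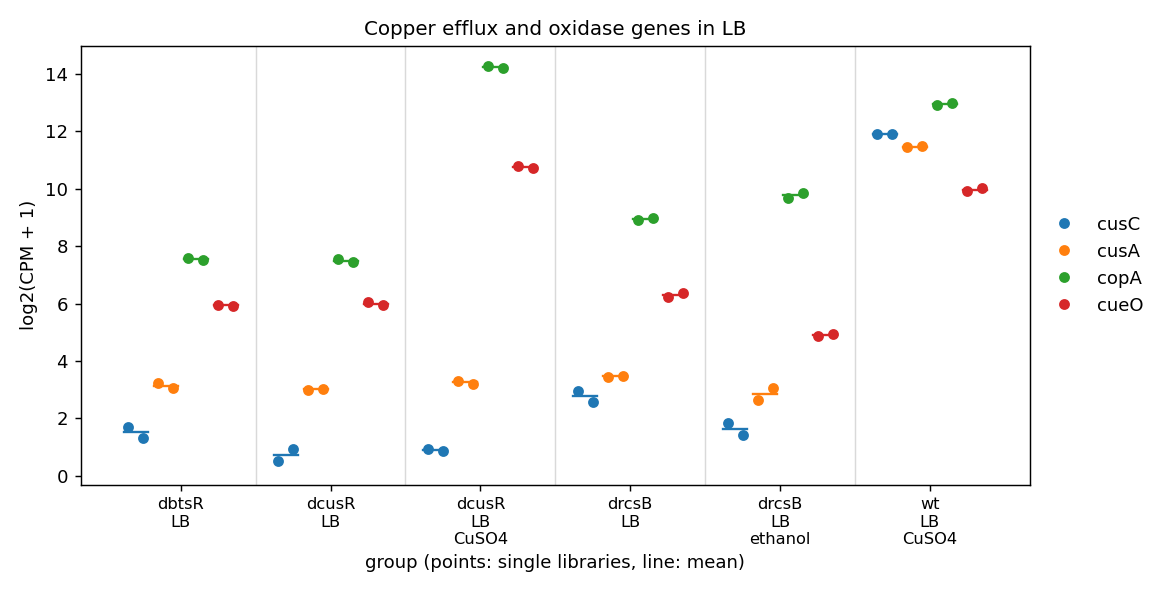
Levels of cusC, cusA, copA and cueO as log2(CPM + 1) on a linear axis in each library of the 6 LB groups, with points for single libraries and a line at the mean of 2. cusC reached 3848 CPM in wt_LB_CuSO4 and 0.869 CPM in dcusR_LB_CuSO4, while copA was at 7968 and 19465 CPM.

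Copper added to the cusR strain in LB asks what the response is without CusR. copA (b0484, 6.76 ± 0.24) rose from 179 ± 7.21 to 19465 ± 631 CPM and cueO (b0123, 4.78 ± 0.14) from 62.8 ± 3.16 to 1726 ± 54.6. Of 11 CueR and copper homeostasis genes 8 rose and 2 fell (9 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0017). cusC stayed low, at 0.684 ± 0.341 and 0.869 ± 0.0402 CPM, and cusA (0.28 ± 0.17, adjusted p = 0.19) did not pass. The lysine decarboxylase genes cadB (8.62 ± 0.47) and cadA (8.32 ± 0.41), zraP (8.46 ± 0.28), the superoxide response gene soxS (5.47 ± 0.18) and the periplasmic protease gene degP (4.83 ± 0.18) rose strongly. All 21 heat shock genes rose (21 higher when adjusted over the list alone, camera adjusted p = 1.5e-12), with the small chaperone genes ibpB (3.24 ± 0.15) and ibpA (2.88 ± 0.09) and clpB (3.19 ± 0.08). Genes under CpxR rose in 14 of 15 (14 higher when adjusted over the list alone, camera adjusted p = 2.3e-09), with yebE (3.89 ± 0.10) and cpxP (3.58 ± 0.12). RpoS-dependent genes rose in 27 of 29 (28 higher when adjusted over the list alone, camera adjusted p = 1.03e-13), with poxB (3.82 ± 0.09) and katE (2.80 ± 0.12).

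SoxRS and MarA genes rose in 16 of 18 and fell in 1 (16 higher and 1 lower when adjusted over the list alone, camera adjusted p = 7.8e-06), with fpr (2.98 ± 0.09) and nfo (2.17 ± 0.11). Arginine genes rose in 12 of 13 (12 higher when adjusted over the list alone, camera adjusted p = 4.9e-06), such as argI (2.51 ± 0.25). The porin gene ompF (-5.95 ± 0.08) fell from 5690.2 ± 73.4 to 92.3 ± 8.91 CPM, and the nitrite reductase genes nirB (-5.55 ± 0.11) and nirC (-6.25 ± 0.14) and the lactate dehydrogenase gene lldD (-4.98 ± 0.12) fell. Aerobic respiration genes fell in 18 of 19 and rose in 1 (1 higher and 18 lower when adjusted over the list alone, camera adjusted p = 7.3e-09), with cyoE (-4.89 ± 0.11) and cyoD (-4.57 ± 0.09). Ribosomal protein genes fell in 50 of 54 (51 lower when adjusted over the list alone, camera adjusted p = 1.8e-11, and adjusted p = 0.15 with an estimated correlation), with rpsB (-1.44 ± 0.08). CRP-dependent sugar genes fell in 29 of 39 and rose in 5 (5 higher and 30 lower when adjusted over the list alone, camera adjusted p = 5.2e-07), with malK (-3.94 ± 0.10). The count was 1206 higher and 1381 lower, 454 and 599 at least 2-fold.

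Ethanol was tested in LB in the rcsB strain only, so the contrast gave the ethanol response without RcsB. Among Rcs-controlled genes, the biofilm and acid resistance genes ymgA (3.81 ± 0.30) and ariR (3.67 ± 0.28) rose, ymgA from 2.42 ± 1.54 CPM and by 4.65 without drcsB_LB replicate 1. osmB (-1.22 ± 0.20), ivy (-0.81 ± 0.09) and the UDP-glucose dehydrogenase gene ugd (-3.49 ± 0.20) fell. The lipoprotein sensor gene rcsF (b0196, 1.14 ± 0.08) rose and rcsC (b2218, -0.75 ± 0.07) and rcsD (b2216, -0.39 ± 0.07) of the phosphorelay fell. The acid shock gene asr (8.53 ± 0.19) rose from 5.22 ± 1.19 to 1926 ± 75.9 CPM and the periplasmic chaperone gene spy (6.73 ± 0.17) from 37.6 ± 3.39 to 3983 ± 168. Heat shock genes rose in 20 of 21 cases (20 higher when adjusted over the list alone, camera adjusted p = 1.3e-09, and adjusted p = 0.059 with an estimated correlation), with ibpB (5.21 ± 0.15), dnaK (4.45 ± 0.12) and clpB (4.45 ± 0.09). All 9 glycerol genes rose (9 higher when adjusted over the list alone, camera adjusted p = 6.1e-06, and adjusted p = 0.086 with an estimated correlation), with glpC (8.13 ± 0.30), glpA (8.08 ± 0.36) and glpD (6.83 ± 0.09).

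All 54 ribosomal protein genes fell (54 lower when adjusted over the list alone, camera adjusted p = 7.4e-17, and adjusted p = 0.078 with an estimated correlation), with rpsJ (-3.91 ± 0.09), rpsS (-3.67 ± 0.16) and rplD (-3.62 ± 0.11). RpoS-dependent genes fell in 27 of 29 (27 lower when adjusted over the list alone, camera adjusted p = 1.5e-08, and adjusted p = 0.078 with an estimated correlation), such as the catalase gene katE (-4.43 ± 0.12), talA (-3.29 ± 0.10) and elaB (-3.22 ± 0.09). The osmoprotectant transport genes yehY (-5.42 ± 0.27) and osmF (-4.86 ± 0.17) fell. Phosphate limitation genes rose in 11 of 16 (11 higher when adjusted over the list alone, camera adjusted p = 8.8e-05), with pstS (5.60 ± 0.11) and pstC (4.62 ± 0.14). SoxRS and MarA genes rose in 16 of 18 (16 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.1e-05, and adjusted p = 0.059 with an estimated correlation), with soxS (6.12 ± 0.19) and sodA (4.33 ± 0.12). Flagellar genes fell in 43 of 54 and rose in 1 (2 higher and 44 lower when adjusted over the list alone, camera adjusted p = 1.4e-05), with fliA (-5.00 ± 0.38). All 9 ATP synthase genes fell (9 lower when adjusted over the list alone, camera adjusted p = 0.00067, and adjusted p = 0.078 with an estimated correlation), with atpC (-1.84 ± 0.08). Branched-chain amino acid genes rose in 15 of 18 (15 higher when adjusted over the list alone, camera adjusted p = 8.6e-05, and adjusted p = 0.078 with an estimated correlation), led by ilvC (4.77 ± 0.10). Of all genes tested, 1398 rose and 1511 fell, 829 and 1038 at least 2-fold. These numbers were 1105 higher and 1994 lower with limma on the deposited log2 TPM.

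The rcsB strain in LB was set against the mean of the btsR and cusR strains in the same medium, a contrast between mutants, since the undeleted strain was not among the unsupplemented LB groups. Of 14 Rcs targets outside the capsule operon, 10 rose and 2 fell (10 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.013, and adjusted p = 0.29 with an estimated correlation), with osmB (2.39 ± 0.16), sra (2.90 ± 0.17), ygdI (1.97 ± 0.14) and ivy (0.83 ± 0.07) higher, ymgD (-1.80 ± 0.26) lower, and mliC (0.15 ± 0.17, adjusted p = 0.48) not past the test. In the phosphorelay rcsD (b2216, -0.77 ± 0.06) and igaA (b3398, -0.66 ± 0.09) were lower, and rcsF (b0196, 0.09 ± 0.07, adjusted p = 0.28) did not pass, or rose with median-of-ratios factors (adjusted p = 0.031) and with the LB libraries alone (adjusted p = 0.044), within a range of 0.031 to 0.61 over all alternatives. The lysine decarboxylase gene cadA (8.36 ± 0.28) stood at 14258 ± 623 CPM against 238 ± 6.23 in dbtsR_LB and 7.88 ± 1.06 in dcusR_LB. All 29 RpoS-dependent genes rose (29 higher when adjusted over the list alone, camera adjusted p = 3.4e-23), with katE (4.56 ± 0.09), fbaB (4.13 ± 0.06) and elaB (3.80 ± 0.07). Acid resistance genes rose in 12 of 17 and fell in 4 (12 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.00032, and adjusted p = 0.11 with an estimated correlation), with slp (5.49 ± 0.08) and glsA (5.55 ± 0.11) higher. The spermidine exporter genes mdtI (5.87 ± 0.15) and mdtJ (5.61 ± 0.19) rose.

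All 38 iron uptake genes fell (38 lower when adjusted over the list alone, camera adjusted p = 1.2e-13), such as fhuF (-4.10 ± 0.21), fecA (-3.82 ± 0.12) and entE (-3.65 ± 0.29). These falls came mostly from dcusR_LB: against dbtsR_LB alone the values of these 3 genes were -1.21, -1.60 and -1.31, with 13 of the list lower and 1 higher, and against dcusR_LB alone -6.99, -6.04 and -6.00, with 38 lower. All 9 glycerol genes fell (9 lower when adjusted over the list alone, camera adjusted p = 8.6e-07, and adjusted p = 0.11 with an estimated correlation), with glpA (-8.76 ± 0.35), glpC (-8.62 ± 0.29) and glpT (-6.87 ± 0.18). Nitrite reductase genes nirB (-6.15 ± 0.11) and nirC (-6.31 ± 0.15) and the pyruvate-induced gene yhjX (-5.70 ± 0.17) fell, the last at 5.33 ± 2.69 CPM against 4749.8 ± 345 in dbtsR_LB and 16.1 ± 1.49 in dcusR_LB. yhjX was at -6.33 without drcsB_LB replicate 1 and nirC at -6.95 without drcsB_LB replicate 2. Aerobic respiration genes fell in 18 of 19 and rose in 1 (1 higher and 18 lower when adjusted over the list alone, camera adjusted p = 2.6e-06), the latter being ndh (1.72 ± 0.06), with 11 lower and 4 higher against dbtsR_LB alone. The dehydrogenase genes aceE (3.54 ± 0.09) and aceF (3.45 ± 0.07) and the flagellin gene fliC (3.94 ± 0.08) rose, and gpmM (-2.53 ± 0.09) fell. All 6 CusR target genes were higher (6 higher when adjusted over the list alone, camera adjusted p = 0.0052, and adjusted p = 0.056 with an estimated correlation), where the reference includes the strain without cusR, and 4 were higher against dbtsR_LB alone. The test gave 1029 genes higher and 1620 lower, 483 and 511 at least 2-fold, 2519 in all against dbtsR_LB alone and 2556 against dcusR_LB alone.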

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

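The tests of the difference between responses were set before the data were examined, whereas the tests on the flagellar genes, the wider tests on dbtsR_0.1xLB replicate 1 and the subtraction of a share from it were chosen after the results were seen.

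The response to acetoacetate differed between wt and the atoC strain in 211 genes by the edgeR test of the difference itself, over 8 libraries. That total depended on the setting, at 17 with only the libraries of the same medium family in the fit and 131 with limma on the log2 TPM. Genes with a response lower in the deletion strain, as log2 differences, were atoE (-6.31), atoB (-4.97), gadE (-2.18), appY (-1.50), stpA (-1.04) and narH (-1.02), and the difference was positive for ychH (1.49), hisC (0.78) and htpX (0.67), of which ychH fell in wt and all 3 rose in the deletion strain. Genes under CpxR differed with a list median of 0.44. The response to pyruvate differed between wt and the btsR strain in 91 genes, with malE (-0.90), glnA (-0.79), argT (-0.69) and cstA (-0.66) among those with a lower response. This number was 446 with only the libraries of the same medium family in the fit and 39 with limma on the log2 TPM. List medians of that difference were -0.52 for nitrogen limitation, -0.46 for CRP-dependent sugar uptake, -0.42 for fatty acid breakdown and -0.53 for tryptophan. These medians include the excess in dbtsR_0.1xLB replicate 1 described below.

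Flagellar genes were lower in the atoC, btsR and cusR strains than in wt, with list medians of -5.17, -5.20, -1.10, -1.05 and -3.14 in the 5 comparisons. Activation by AtoC with acetoacetate is argued against, since the median interaction over the list was 0.24, the deletion effect being no deeper with acetoacetate. The RpoS list, used as a sign of a growth state shared by the deletion cultures, had no shared direction. It fell in the atoC strain with acetoacetate (median -0.44, camera adjusted p = 6.99e-13) and rose in the cusR strain (median 0.84, camera adjusted p = 5.61e-09). These cultures differed in medium, and copper itself raised most RpoS genes in the cusR strain. The list therefore cannot tell growth state from copper stress, and a shared growth state stays open. A difference between stocks of wt and of the deletion strains that acts through flhD and flhC, the genes of the flagellar master regulator, stays open. Their mean fell in each of the 5 comparisons, between -1.46 ± 0.19 and -0.94 ± 0.15 (n = 2 libraries per group). These standard errors treat flhD and flhC as independent, though both were measured in the same libraries, and may be too small. Both genes belong to the flagellar list, so their fall is part of the pattern and supports no source of it. The loss of each regulator itself stays open, untested, because strain and stock coincide in these groups.

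In dbtsR_0.1xLB replicate 1, transcripts abundant in dcusR_LB_CuSO4 were in excess over replicate 2, by a median of 1.75% of their level there over 17 genes (1.39 to 2.13%), while drcsB_LB_ethanol as a source gave 0.698%. A difference between the replicate cultures is argued against, since the upper quartile of the share was only 1.24 times the lower over 16 less abundant genes. Reads or RNA of the copper-treated cusR strain may be the source at a fixed share: these 16 genes gave a median of 1.68%, above 0 in 16 of 16, and the narrower test set beforehand held 1 gene, at 2.18%. At that share 3.5 reads of btsR would be carried over, and 4 were counted. With the share subtracted, btsT in the btsR strain against wt moved from 1.19 to -0.20, and at what step of the work the excess arose was not tested.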

How the results depend on the processing

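The subtraction of a fixed share from dbtsR_0.1xLB replicate 1 and the crossed pairing were chosen after seeing the data, and the other alternatives were not. Median-of-ratios factors, no low-count filter, the stricter filter and each reference strain alone left every total of changed genes within 1.5 times its value. With only the libraries of the same medium family in the fit, and so fewer residual degrees of freedom, the counts became 655 (datoC against wt with acetoacetate), 583 (with LiCl), 95 (acetoacetate in wt), 209 (acetoacetate in datoC), 17 (its interaction), 177 (LiCl), 925 (dbtsR against wt in 0.1x LB), 569 (pyruvate in wt), 489 (pyruvate in dbtsR) and 446 (its interaction). limma on the log2 TPM gave 177 for acetoacetate in wt, 131 for its interaction, 361 for LiCl, 138 for pyruvate in wt, 45 in dbtsR and 39 for its interaction, and DESeq2 gave 141 for the last. Leaving out each library in turn, which leaves a lone library assumed to vary like the other groups, gave 760 to 1204 changed genes for datoC against wt with acetoacetate, 552 to 916 with LiCl, 147 to 985 for acetoacetate in wt, 262 to 435 in datoC and 69 to 784 for the interaction. It gave 177 to 525 for LiCl, 193 to 288 for dbtsR against wt, 60 to 83 for pyruvate in wt, 21 to 83 in dbtsR and 24 to 93 for the interaction. The cause of these moves was not tested. Totals moved in both directions, and fewer libraries or degrees of freedom do not by themselves account for a rise. With the same medium family only, totals fell in the M9 comparisons and rose in those in 0.1x LB, whose family also held dbtsR_LB. Duplicates lay furthest apart in wt_M9_acetoacetate_LiCl, at 48.3 times the variance of counting alone, against 1.73 to 4.47 times in the 0.1x LB groups. The main fit took the spread of a gene from all groups together.

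With an estimated correlation, camera kept 78 of 103 list calls. Of 355 calls of named genes, 3 were lost or turned when a library was left out. The naming rule picked many of these genes for large changes in the same data, which makes losses rare by selection. They do not stand for all called genes. btsT in dbtsR against wt in 0.1x LB changed direction, from 1.19 to -0.27 without dbtsR_0.1xLB replicate 1 (1.94 without replicate 2 of that group) and to -0.20 with the share subtracted. limma on the log2 TPM moved the median log2 change of all genes by over 0.1 in 4 comparisons, from 0.003 to -0.39 for 0.1x LB against LB, -0.07 to -0.32 for ethanol, 0.05 to 0.16 for dcusR against wt with copper and -0.04 to 0.08 for copper in dcusR. The fold changes given are relative to the TMM scale. The replicate numbers gave no pairing common to the comparisons: deviations of same-numbered libraries correlated between -0.225 and 0.239. The highest value was that between wt_M9_acetoacetate_LiCl and wt_M9_LiCl, where a shared deviation cannot be excluded. A replicate block moved no total by over 1.5 times, and most for acetoacetate in wt, from 348 to 428. Crossed numbers gave 1050 instead of 1033 genes for datoC against wt with LiCl and 2592 instead of 2587 for copper in dcusR. No paired analysis was possible in the comparisons that use datoC_M9_acetoacetate_LiCl, because both of its columns carry the number 1. Removal of rRNA and tRNA genes was not run, as the counts hold none. With 2 libraries per group, depth and spread limit genes near the floor of 3 counts, such as atoD and atoA without acetoacetate.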

Other observations

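Among the tests on the rcsB strain, that on scaling was chosen after the result was seen, and the levels of genes across groups were looked at with no test planned.

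btsT stood at 12346 ± 283 CPM in dcusR_LB and 7687 ± 329.8 in wt_LB_CuSO4, at 13.1 ± 0.135 in dbtsR_LB and 74.3 ± 1.47 in drcsB_LB, where btsR is intact, and at 14.7 ± 0.299 in wt_0.1xLB_pyruvate (mean ± SD, n = 2). yhjX, the transporter gene of the other pyruvate sensing system, stood at 4749.8 ± 345 CPM in dbtsR_LB and 16.1 ± 1.49 in dcusR_LB. cusC was high in M9 without added copper, at 2651 ± 36.3 CPM in wt_M9_LiCl and 977 ± 113 in datoC_M9, against 1.89 ± 0.571 in dbtsR_LB. fliC stood at 33.2 ± 4.78 CPM in dbtsR_LB, 29.6 ± 1.13 in dcusR_LB and 479 ± 15.6 in drcsB_LB. raiA, for a factor that binds resting ribosomes, reached 83295 ± 36.1 CPM in drcsB_LB_ethanol against 10534 ± 7.91 in drcsB_LB. Coding genes under 300 nt differed from those of 600 nt or more in their median log2 change for 0.1x LB against LB in the btsR strain, 0.50 against -0.23, and between the duplicates of datoC_M9_acetoacetate_LiCl, 0.31 against -0.05.

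RpoS-dependent genes were higher in drcsB_LB than in the other deletion strains in LB, with a list median of 3.19. Cultures taken at a later state of growth were predicted to have lower ribosomal protein genes, the only marker used. Against dbtsR_LB these genes went against the prediction, with a median of 0.053, 13 higher and 13 lower. The RpoS list median there was 3.41. The marker cannot decide there, since its share of counts was already 5.01 and 5.12% in dbtsR_LB, against 4.63 and 4.68% in drcsB_LB. That share was 5.8 and 5.78% in dbtsR_0.1xLB, where RpoS-dependent genes were also higher than in dbtsR_LB. Against dcusR_LB the ribosomal median was -1.06, as a later state would give. A later state of growth stays open against both references. A shift of the scaling by a few abundant genes is argued against by its size, as far as the 2 sets of factors differ. The median log2 change of all genes was -0.146 with TMM and -0.05 with median-of-ratios factors, against a lower quartile of 2.75 for the RpoS list. With the latter factors 29 of 29 members were called higher, a count that so small a move could hardly change. The loss of RcsB stays open and may contribute: Rcs targets outside the capsule operon had medians of 1.43 and 1.73 against the references, whereas lower values were predicted without RcsB. That prediction is weakened by RpoS acting on members of this list and by its rise in 0.1x LB against LB with rcsB intact, with a median of 3.13.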
